A study of Mus musculus with 4 samples.

How the data were processed

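Antral epithelial glands came from mice given recombinant R-Spondin 1 (100 µg per mouse, intravenously) or PBS, and total RNA was extracted with Trizol and labelled with Agilent's Quick-Amp kit, per the labels' protocols. The labels name a 1st and a 2nd biological replicate for each treatment. How many mice went into each RNA, their sex and the time after injection are not given in the sources used here. RNA pairs I against I and II against II were hybridised on Agilent-014868 whole mouse 4x44K arrays, each pair on 2 arrays with Cy3 and Cy5 exchanged, so that 4 arrays held 4 RNAs. All 4 lay on 1 slide, which leaves no slide effect to test.

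The authors scanned the arrays and deposited the spot intensity values, per the file headers made with Agilent Feature Extraction 11.5.1.1, with mean signals, local background signals and flags for each spot and channel on a linear scale. The tool is also the one in the submitters' processing notes, without a version. The authors also deposited a table of log10 ratios of red over green for each array, which equals the scanner files' own log ratio to within 0.00155 on the log2 scale. Its scale and direction follow from that match, and it holds no further centring. Probe positions in the files are on mm9.

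Starting from the mean signals and the median local background, the background was corrected by normexp with an offset of 50 and the log2 ratios were normalised within each array by loess, with control spots at weight 0 (limma 3.58.1 in R 4.3.3). Control spots and 105 to 146 spots per array marked by the scanner software as outliers were left out, and spots of the same probe were averaged. Signs were turned so that every ratio reads R-spondin over PBS, and the 2 dye-swapped arrays of a pair, which hold the same RNA, were averaged into 1 replicate, which cancels a dye effect. Of 41174 probes 17225 were well above background on all 4 arrays in the R-spondin channel or on all 4 in the PBS channel and were kept. The brightest probe stood for its gene, which left 12202 genes, 10623 of them with a gene symbol. Gene names are those of the array design, and 27668 probes matched a RefSeq transcript by accession in a table of GRCm38.p6, which was used for names alone. Base composition was taken from the 60-base probe sequences in the files.

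The test was limma's lmFit and eBayes on the 2 replicate ratios against 0, two-sided, with Benjamini-Hochberg adjustment over the 12202 genes at 0.05. Each array sets the RNAs of a replicate side by side, so the pairing comes from the hybridisation itself. With 2 replicates there is 1 residual degree of freedom, and limma's estimate of the prior degrees of freedom was infinite, so every gene received the same SD. Gene lists were tested with camera at a preset correlation of 0.01, two-sided, adjusted over 30 lists, and beside it with an estimated correlation and with fry. Medians of each list were also ranked against 10000 random lists of the same size and intensity: the S phase, G2/M, ribosome biogenesis and Wnt target lists stood at percentile 100, and the endocrine, surface mucous, intestinal, red blood cell and pancreatic acinar lists at 0. The rank uses the mean of the replicates and takes no account of their disagreement: 8 of the 12 acinar genes had opposite signs.

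Genes named in the text follow a rule fixed before the data were examined: up to 12 higher and 12 lower genes past the threshold with a symbol and the same sign on 4 arrays, places left being filled with the largest mean ratios of the same sign on 4 arrays, then up to 4 members per list and Axin2, Lgr5, Mki67, Muc5ac, Muc6, Gast and Rspo3. Genes above background on all 4 arrays in one RNA and on 0 in the other have only a bound. There were 2, both without a symbol and named here after their values were seen: 2310005G13Rik, at least 1.64-fold lower with R-spondin, and 3110082I17Rik, at least 1.12-fold higher, from channel signals after loess and Aquantile against the lowest signal well above background (limma adjusted p = 0.9997 for both).

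The functions were tested on simulated data for this comparison, with 12202 genes, the same spread and a dye effect: of 50 genes changed by a log2 ratio of 1, 12% were recovered, of 50 at 1.5, 60%, of 50 at 2, 94%, and of 50 at 3, 100%, with 2 false calls. Among 500 unchanged lists 1.8% had a camera p under 0.05. The simulated genes varied independently of each other and had no trend with probe GC content, unlike the data. This share therefore does not tell the rate for lists of correlated genes. All simulated genes also had the same SD, as the test assumes. The recovered shares and the 2 false calls therefore hold under that assumption and do not tell the rates in the data.

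Alternatives covered the background correction, the normalisation, the filter, the choice of probe, the variance model, the use of single arrays, one dye orientation at a time, the unpaired RNAs, the deposited ratio table, other thresholds and each replicate left out. Chosen after seeing the data were the removal of the trend with probe GC content, the restriction to calls with the same sign on 4 arrays and a random block without a dye term.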

Results

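Glands of the gastric antrum, the lower part of the stomach that carries gastrin-producing endocrine cells, were isolated from mice injected intravenously with recombinant R-Spondin 1, a secreted protein that amplifies Wnt signalling through Lgr receptors, at 100 µg per mouse, or with PBS. The epithelial RNA of each treatment was compared on Agilent whole mouse 4x44K two-colour arrays. There were 2 biological replicates, each a pair of 1 R-spondin and 1 PBS RNA, and each pair was hybridised on 2 arrays with the dyes exchanged, which gave 4 arrays on 1 slide. Each array held 43379 spots outside the controls. Between 41.5% and 44.8% of these spots were well above background in the green channel and between 48.2% and 60.1% in the red, with 0 saturated spots. After the filter on dim probes 12202 genes were kept, and the number of replicates (n = 2 ratios) limits the precision of every value. Values are log2 ratios of R-spondin over PBS, given as the mean of the replicates ± SD.

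The comparison asks which genes of the antral epithelium respond to injected R-spondin. By camera with its preset correlation, lists of cell division and ribosome production genes rose after R-spondin and endocrine cell genes fell. Each had an adjusted p = 0.541 with an estimated correlation, where 0 of 30 lists passed. The estimated form draws on 1 residual degree of freedom and can hardly pass for any list, so it decides little here or below. The preset form in turn takes little account of disagreement between the replicates. With limma, 12 of the 12202 genes passed a Benjamini-Hochberg adjusted p under 0.05, 5 of them higher and 7 lower. The inducible heat shock chaperone Hspa1a rose most, by 2.54 ± 1.35 (SD, n = 2; 5.83-fold; adjusted p = 1.7e-06). The antral hormone gene Gast, which encodes gastrin, fell, with a mean of -2.07 ± 0.89 (SD, n = 2; 4.2-fold lower; adjusted p = 7.1e-04). Both had the same sign on all 4 arrays.

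Khdc1a, a KH domain gene best known from oocytes, rose with ratios of 2.52 in replicate 1 and 2.29 in replicate 2 (adjusted p = 8.0e-06). The mast cell protease genes Mcpt1 and Cma1 rose by 1.89 ± 0.05 and 1.82 ± 0.60 (SD, n = 2; adjusted p = 0.00351 and 0.00634). Xlr4b, of an X-linked lymphocyte-regulated family, rose by 1.67 ± 0.84 (SD, n = 2; adjusted p = 0.0245). The probe of Hspa1a lies on chromosome 17, 35106766 to 35106825 of mm9, the build the scanner files name, that of Khdc1a on chromosome 1, 21342143 to 21342202, that of Mcpt1 on chromosome 14, 56638928 to 56638987, that of Cma1 on chromosome 14, 56560454 to 56560513 and that of Xlr4b on chromosome X, 70467736 to 70467792. Hspa1a has a near-identical neighbour, Hspa1b, and the Mcpt and Xlr4 genes are families, so a probe of one may also bind transcripts of another.

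Among the genes that fell, Chia, which encodes acidic mammalian chitinase and is now named Chia1, had a mean of -2.03 ± 0.73 and Fcgbp, a protein of the mucus layer, -1.96 ± 0.59 (SD, n = 2; adjusted p = 9.4e-04 and 0.00193). Their probes lie on chromosome 3, 105934967 to 105935026 and chromosome 7, 28905517 to 28905576, and that of Gast on chromosome 11, 100197806 to 100197865 (mm9). The other 4 genes past the threshold encode digestive enzymes of the pancreas, and they were named after their values were seen because their signs differed between replicates. Cpb1, a carboxypeptidase, had ratios of 0.89 and -4.66 in replicates 1 and 2, Ctrc 0.44 and -3.92, Pnlip, the pancreatic lipase, 0.50 and -3.95 and Try5, a trypsin, 0.40 and -3.82. Their adjusted p ran from 0.00351 to 0.0173, and they were lower in replicate 2 alone.

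The next places in the naming rule went to genes with the same sign on all 4 arrays that did not pass. On the high side these were the CTP synthase gene Ctps (1.59 ± 0.19, adjusted p = 0.0557), the chromatin protein gene Hmgb2 (1.57 ± 1.23), the exonuclease gene Exo1 (1.54 ± 0.73), Nop56 of the small nucleolar ribonucleoproteins (1.52 ± 0.29), the phospholipase gene Pla2g5 (1.51 ± 0.49), the mast cell protease gene Mcpt4 (1.497 ± 0.30) and the replicative helicase gene Mcm6 (1.43 ± 0.55, adjusted p = 0.178). On the low side were the enkephalin precursor gene Penk (-1.39 ± 0.59, adjusted p = 0.236), Sgk2 (-1.35 ± 0.14), Sprr1a (-1.32 ± 1.11), Hamp2 (-1.32 ± 0.18), the prohormone convertase gene Pcsk2 (-1.31 ± 0.94), the cytokine gene Il33 (-1.29 ± 0.81), Slurp1 (-1.28 ± 0.34), Sycn (-1.28 ± 0.27) and the cholecystokinin gene Cck (-1.27 ± 0.32, adjusted p = 0.311). The log2 level of Sycn was highest in the PBS RNA of replicate 2, as were those of the pancreatic enzyme genes above. It was 11.0 there, against 9.75 in the PBS RNA of replicate 1 and 8.66 and 9.54 in the R-spondin RNAs. Of the 49 other probes of the genes picked by the naming rule that passed the filter, 49 had the sign of the chosen probe in the mean of the replicates. Of these 11 were under 0.5 times its size and 19 had opposite signs in the 2 replicates. Nop56 had a mean of 0.13 at its other probe, Hmgb2 0.98, Pcsk2 -0.69, Chia -1.50 (adjusted p = 0.0722 over every probe) and Cma1 1.20 (adjusted p = 0.393). The last 2 did not pass there.

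**Figure D1:**
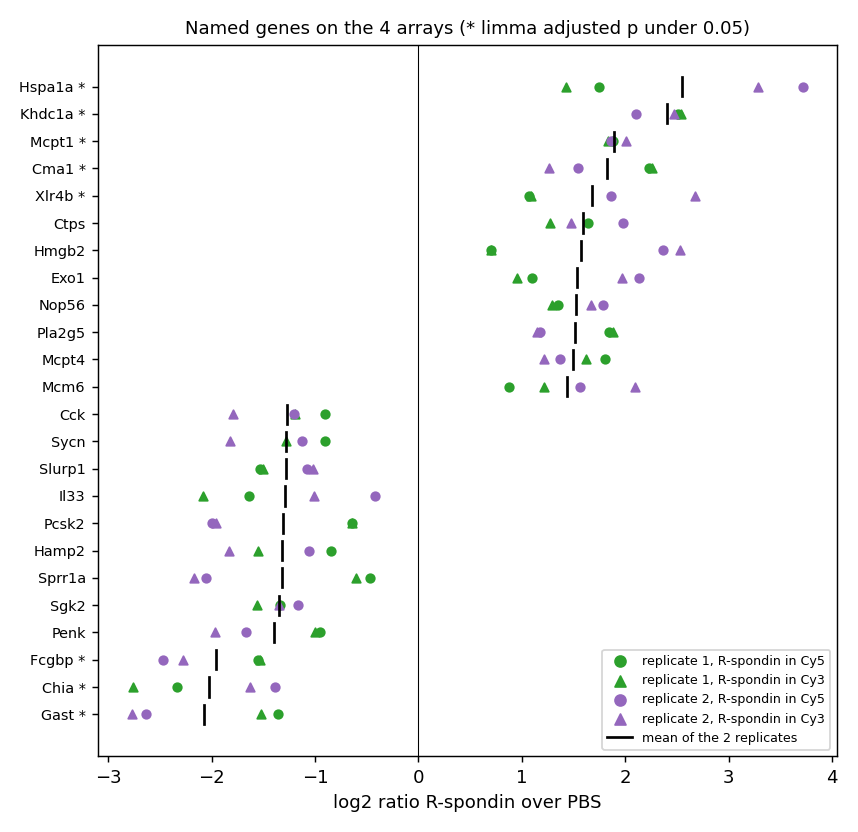
Log2 ratio of R-spondin over PBS (horizontal axis) of the 24 named genes with the same sign on 4 arrays, with 1 symbol per array (colour for the replicate, shape for the dye of the R-spondin RNA), a bar at the mean of the 2 replicates and an asterisk for a limma adjusted p under 0.05. Hspa1a has the highest mean, 2.54, and Gast the lowest, -2.07.

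The test drew on 1 residual degree of freedom, and limma gave every gene the same SD of 0.56, so that it acted as a threshold near a log2 ratio of 1.67 and did not weigh a gene's own difference between replicates. No gene passed with median centring in place of loess, with no filter on dim probes, with the 4 arrays taken as independent or with the 4 RNA samples unpaired (104, 1208, 1647 and 522 genes at an unadjusted p under 0.05, against 586), and with Agilent's processed signals 15 genes were higher and 2 lower, without Gast, Chia and Fcgbp among them.

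The replicates were compared over all genes. Dye-swapped arrays of the same RNA pair correlated well once their signs were turned, with Pearson's r across genes of 0.87 in replicate 1 and 0.90 in replicate 2. The ratios of replicate 1 and replicate 2 did not correlate, r = -0.07 across genes, which are not independent replicates. Of the 12202 genes 23.6% were higher in both replicates, 17.7% were lower in both and the rest had opposite signs. The ratio followed the GC content of the probe in opposite ways, with r = 0.26 across genes in replicate 1 and r = -0.41 in replicate 2. The plot by GC content shows the medians. Turning the sign of replicate 2 left 0 genes past the limma threshold, with 744 genes at an unadjusted p under 0.05.

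**Figure D2:**
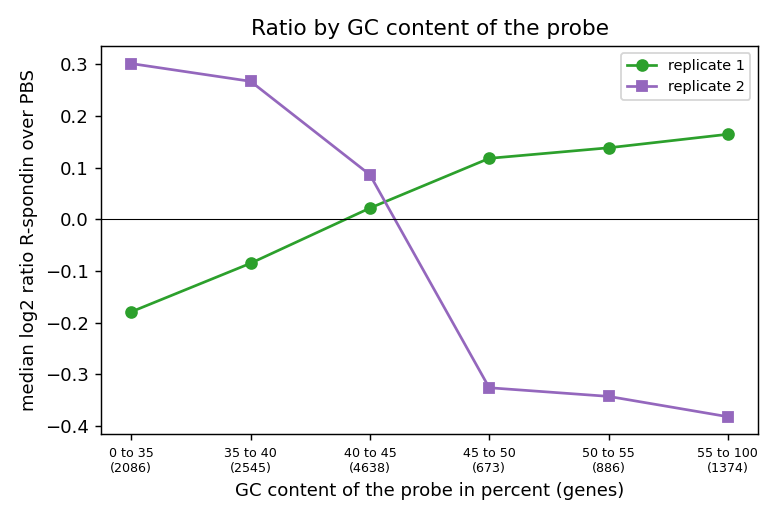
Median log2 ratio of R-spondin over PBS (vertical axis) of genes binned by the GC content of their probe in percent (horizontal axis, with the number of genes), in replicate 1 (circles) and replicate 2 (squares). From the lowest to the highest bin the median goes from -0.18 to 0.16 in replicate 1 and from 0.30 to -0.38 in replicate 2.

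**Figure D3:**
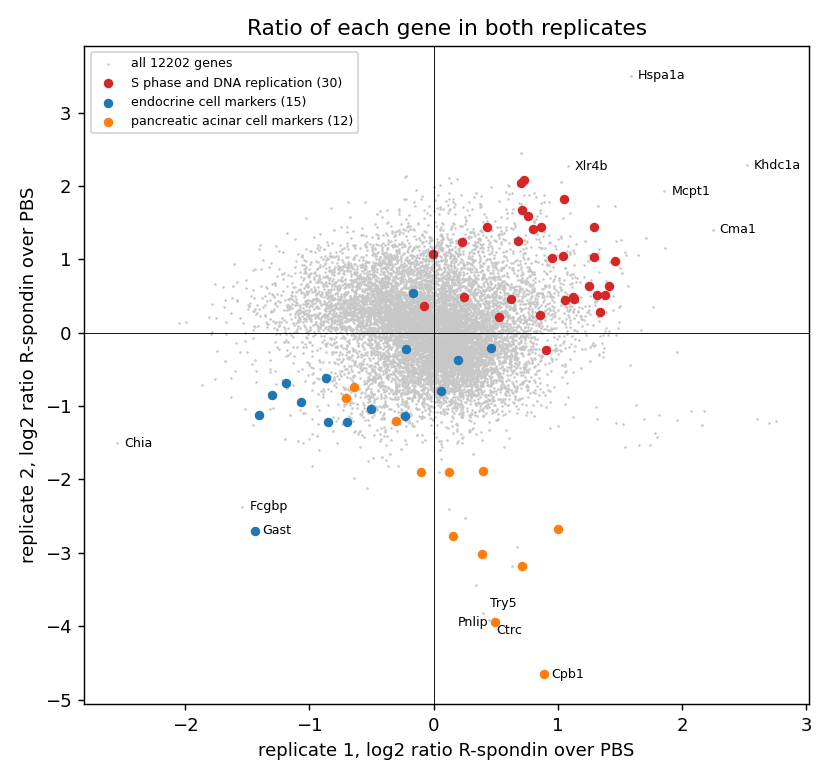
Log2 ratio of R-spondin over PBS in replicate 1 (horizontal axis) and replicate 2 (vertical axis) for 12202 genes (grey) and the members of 3 gene lists (coloured), with the 12 genes past the limma threshold named. Of the S phase genes 27 lie above 0 in both replicates, 11 endocrine genes lie below 0 in both, and 8 of the 12 pancreatic genes have opposite signs in the replicates.

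Among 30 gene lists fixed before the data were examined, genes of S phase and DNA replication rose with the lowest camera p. Of 30 measured members 27 were higher in both replicates, 0 were lower in both, and the list's median was 0.88 in replicate 1 and 1.00 in replicate 2 (camera adjusted p = 2.0e-29; adjusted p = 0.541 with an estimated correlation). With limma 0 members passed over all genes (21 at an unadjusted p under 0.05) and 18 rose when adjusted over the list alone. They included the helicase genes Mcm6 (1.43 ± 0.55), Mcm4 (1.37 ± 0.95) and Mcm3 (1.37 ± 0.10) and the primase gene Prim1 (1.40 ± 0.95; SD, n = 2). The G2/M and mitosis genes also rose, with 22 of 29 higher in both replicates and medians of 0.49 in replicate 1 and 0.90 in replicate 2 (camera adjusted p = 1.9e-16; adjusted p = 0.541 with an estimated correlation). With limma 0 of them passed adjusted over the list alone (11 at an unadjusted p under 0.05). Birc5, the gene of survivin, had ratios of 0.89 and 1.37 and cyclin A2, Ccna2, 0.12 and 1.91. The proliferation marker Mki67 had ratios of -0.21 and 1.00 at its brightest probe and 0.48 and 0.77 at its other probe.

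Ribosome biogenesis genes rose as well: 23 of 25 were higher in both replicates, with medians of 0.87 in replicate 1 and 0.56 in replicate 2 (camera adjusted p = 4.3e-17; adjusted p = 0.541 with an estimated correlation). Adjusted over the list alone 2 rose, Nop56 (1.52 ± 0.29) and nucleophosmin, Npm1 (1.23 ± 1.08; SD, n = 2), while Gar1 and Ppan, with means of 0.99 ± 0.39 and 0.97 ± 0.67, did not pass. The other probe of Nop56 had ratios of 0.03 and 0.22, so its rise rests on 1 probe.

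Wnt/beta-catenin target genes rose, with 13 of 18 measured members higher in both replicates, 1 lower in both and medians of 0.88 in replicate 1 and 0.47 in replicate 2 (camera adjusted p = 3.9e-09; adjusted p = 0.541 with an estimated correlation). With limma 0 members passed over all genes (7 at an unadjusted p under 0.05), and 4 rose adjusted over the list alone: Cdca7 (1.35 ± 0.41), Myc (1.19 ± 0.32), the progenitor transcription factor Sox9 (1.11 ± 0.03) and the Wnt feedback inhibitor Nkd1 (1.06 ± 1.01; SD, n = 2). At other probes Myc had means of 1.13 and 0.42 and Sox9 of 1.07 and 0.31. Division genes rose as well, and whether the Wnt target list rose apart from them was not tested. Rnf43, which removes Wnt receptors from the cell surface, had ratios of 0.77 and 0.85. Axin2, a widely used Wnt target, and Rspo3 were not well above background on any of the 4 arrays in either RNA. The stem cell receptor gene Lgr5 had ratios of -0.17 and 0.32. The list of gastric stem or progenitor markers rose with a median of 0.18, 0.15 in replicate 1 and 0.41 in replicate 2 (camera adjusted p = 0.0273; adjusted p = 0.619 with an estimated correlation), and 6 of 14 members were higher in both replicates. Stmn1, which is also a gene of dividing cells, had a mean of 1.03 ± 0.05, Tnfrsf19 0.62 ± 0.18 and Bhlha15 -0.62 ± 0.03. Wnt and R-spondin pathway components did not pass (median 0.05, camera adjusted p = 0.727), with ratios of -0.31 and 1.32 for Lrp5 and -0.66 and -0.30 for Fzd5.

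Endocrine cell markers fell. Of 15 measured members 11 were lower in both replicates and 0 were higher in both, with medians of -0.70 in replicate 1 and -0.84 in replicate 2 (camera adjusted p = 5.5e-13; adjusted p = 0.541 with an estimated correlation). Gast passed over all genes, and 7 fell adjusted over the list alone, among them the granin gene Chgb (-1.26 ± 0.20), somatostatin, Sst (-1.03 ± 0.26), and Cpe, which trims prohormones (-1.07 ± 0.32; SD, n = 2). Pcsk2 and Cck, named above, are also expressed in endocrine cells. Sst, Chgb and Cpe are also expressed in pancreatic islets. The pancreatic acinar list had medians of 0.27 in replicate 1 and -2.28 in replicate 2 and the intestinal list of -0.39 in replicate 1 and -0.81 in replicate 2.

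Surface mucous cell markers fell, with 6 of 13 lower in both replicates, 0 higher in both and medians of -0.66 in replicate 1 and -0.45 in replicate 2 (camera adjusted p = 1.1e-04; adjusted p = 0.541 with an estimated correlation). With limma 0 passed adjusted over the list alone (4 at an unadjusted p under 0.05). The mucin gene Muc5ac had ratios of -1.46 and -0.43, gastrokine 1, Gkn1, -0.70 and -0.98, Psca -0.39 and -1.33 and Capn9 -0.48 and -1.39. Of the other members 7 had opposite signs in the replicates, among them Anxa10 with -1.02 and 1.57, Krt20 with -0.69 and 1.03, Tspan8 with -0.53 and 0.69 and Vsig1 with -0.72 and 0.23. These 4 were named after their values were seen. Mucous neck and deep gland markers did not pass (median 0.00094, camera adjusted p = 0.723): Muc6 had ratios of 0.05 and -0.59, Tff2 -0.52 and -0.55 and Creb3l4 0.70 and 0.90. Chief cell markers fell (median -0.35, -0.35 in replicate 1 and -0.61 in replicate 2; camera adjusted p = 0.00148; adjusted p = 0.541 with an estimated correlation), with 5 of 8 lower in both replicates, led by Chia and with pepsinogen C, Pgc, at -0.45 ± 0.41. Parietal cell markers did not pass (camera adjusted p = 0.139), although the proton pump genes Atp4a and Atp4b had means of -1.09 ± 0.22 and -0.996 ± 1.06, against 0.73 ± 0.31 for Kcnq1. Tuft cell markers fell (median -0.30, camera adjusted p = 0.00714; adjusted p = 0.637 with an estimated correlation), but their medians were 0.11 in replicate 1 and -0.65 in replicate 2 and 3 of 12 were lower in both.

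Markers of tissue outside the antral epithelium differed between the PBS RNAs. The pancreatic acinar genes fell over both replicates together (camera adjusted p = 8.5e-23; adjusted p = 0.541 with an estimated correlation), yet their median was 0.27 in replicate 1 and -2.28 in replicate 2, with 8 of 12 of opposite sign in the replicates and 4 lower in both. Their median log2 level was 11.6 in the PBS RNA of replicate 2, against 7.33 in that of replicate 1 and 7.67 and 8.73 in the R-spondin RNAs. Red blood cell genes fell too (median -1.06, 3 of 10 genes on the array, camera adjusted p = 0.00181; adjusted p = 0.56 with an estimated correlation), with ratios of -0.38 and -1.73 for Hba-a1. With no filter on dim probes their median was 0.01 and they did not pass (adjusted p = 0.687). Antimicrobial and mucosal defence genes fell (median -0.38, camera adjusted p = 6.9e-06; adjusted p = 0.541 with an estimated correlation), with 7 of 14 lower in both replicates, led by Fcgbp, and medians of -0.07 in replicate 1 and -0.53 in replicate 2. Reg1, also abundant in pancreas, had ratios of 0.12 and -2.40. Intestinal epithelial markers fell (median -0.59, camera adjusted p = 9.0e-06; adjusted p = 0.541 with an estimated correlation), with 8 of 11 lower in both, including Cck, Apoa1 (-1.07 ± 0.68) and Alpi (-0.87 ± 0.68). The intestinal medians were -0.39 in replicate 1 and -0.81 in replicate 2. With no filter, which adds dim genes, the medians of the antimicrobial and intestinal lists were -0.07 and -0.06. Immune cell markers rose by camera (adjusted p = 0.0179; adjusted p = 0.706 with an estimated correlation), with Mcpt1 and Mcpt2 (1.20 ± 0.39; SD, n = 2) passing over the list alone, but their median was 0.45 in replicate 1 and -0.20 in replicate 2. Fibroblast and smooth muscle (camera adjusted p = 0.139), endothelial (0.938), squamous (0.326) and sex-linked (0.0505) lists did not pass.

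**Figure D4:**
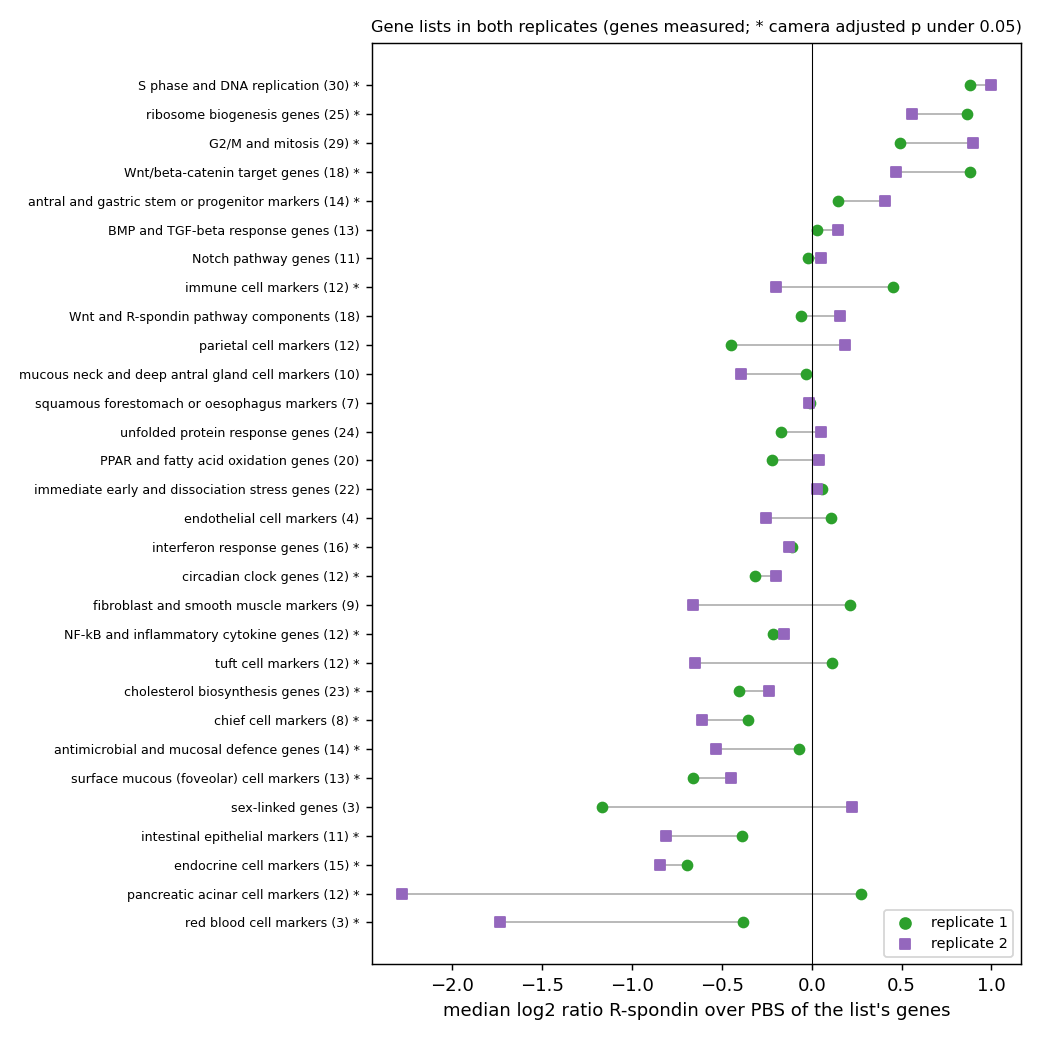
Median log2 ratio of R-spondin over PBS (horizontal axis) of each of the 30 gene lists (rows, with the number of genes measured) in replicate 1 (circles) and replicate 2 (squares), with an asterisk for a camera adjusted p under 0.05. S phase genes lie above 0 in both replicates, at 0.88 and 1.00, and the pancreatic genes lie far apart, at 0.27 and -2.28.

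Cholesterol biosynthesis genes fell (median -0.30, -0.40 in replicate 1 and -0.24 in replicate 2; camera adjusted p = 9.4e-04; adjusted p = 0.541 with an estimated correlation), with 10 of 23 lower in both replicates and Mvd at -0.97 ± 0.37. Circadian clock genes fell (median -0.16, -0.32 in replicate 1 and -0.20 in replicate 2; camera adjusted p = 0.0179; adjusted p = 0.541 with an estimated correlation), with Nr1d1 at -0.998 ± 0.51 (-0.25 at its other probe) and Dbp at -0.64 ± 0.17. NF-kB and cytokine genes (median -0.24, -0.21 in replicate 1 and -0.16 in replicate 2; camera adjusted p = 0.015) and interferon response genes (median -0.15, -0.11 in replicate 1 and -0.13 in replicate 2; camera adjusted p = 0.0274) fell, each with an adjusted p = 0.541 with an estimated correlation. In the NF-kB list 5 of 12 measured members were lower in both replicates and 3 higher in both. In the interferon list 5 of 16 were lower in both and 1 higher in both. Il33 was the member of the NF-kB list that passed over its list alone, and Igtp of the interferon list had a mean of -0.72 ± 0.57. Immediate early and dissociation stress genes did not pass as a list (camera adjusted p = 0.103, median -0.09 and mean 0.18), although the heat shock genes Hspa1a, Hsph1 (1.36 ± 0.38) and Hspa1b (1.30 ± 0.37; SD, n = 2) rose adjusted over the list alone. Whether the isolation of the glands contributed to the rise of these heat shock genes was not tested. Notch (camera adjusted p = 0.974, with Hey1 at 0.65 ± 0.20), BMP and TGF-beta (0.607, with Id2 at 1.06 ± 0.97), unfolded protein (0.469) and PPAR and fatty acid oxidation genes (0.723, with Acot1 at 1.097 ± 0.66) did not pass.

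Altogether 6 of the 30 lists rose and 12 fell by camera with its preset correlation. That p sets a list's genes against the other genes and takes little account of disagreement between the replicates. The pancreatic acinar, tuft and immune lists passed with medians of opposite sign in the 2 replicates. Against the preset of 0.01, the estimated correlation was -0.03 for S phase and 0.17 for G2/M genes. It was 0.39 for tuft, 0.67 for immune and 1 for acinar genes. For the parietal, deep gland, Notch and stress lists, which did not pass, the median and the test differed in sign. The calls of the stem marker, interferon, NF-kB, immune and red blood cell lists held in 16, 15, 15, 13 and 14 of 17 other settings. With a correlation estimated from the same 1 residual degree of freedom 0 lists passed, and with fry 0 passed (lowest adjusted p = 0.541 and 0.404), a design in which these tests can hardly pass.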

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

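The test for a sample far from the others was run on the 4 arrays of each of the 135 named genes and on the median of each of the 30 lists. It set apart 1 gene, Khdc1a, whose array of replicate 2 with the R-spondin RNA in Cy5 read 2.10, against 2.51 and 2.53 on the arrays of replicate 1 and 2.47 on the other array of replicate 2. The gap to the nearest array was 0.842 of the whole range, above Dixon's 95% critical value for 4 samples. Chance sets apart about 5% of groups of 4, and arrays of the same RNA pair are not independent. All 4 values were above 2.1.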

How the results depend on the processing

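Alternatives other than the GC correction, the same-sign restriction and the random block without a dye term were planned. The S phase, G2/M, ribosome biogenesis, Wnt target, endocrine and surface mucous lists passed camera in the same direction under all 17 other ways of processing and fitting that give a test, with medians from 0.90 to 1.13, 0.63 to 0.86, 0.66 to 0.92, 0.52 to 0.88, -0.99 to -0.33 and -0.52 to -0.35. With an estimated correlation the medians of the 6 lists stand as they were (0.94, 0.72, 0.76, 0.67, -0.77 and -0.45) with adjusted p = 0.541 for each, and with fry the adjusted p was 0.404, 0.562, 0.418, 0.418, 0.418 and 0.588, because both draw on 1 residual degree of freedom. The chief, tuft, antimicrobial, intestinal, cholesterol, circadian and pancreatic acinar lists also passed camera in the same direction under all 17. The tuft and acinar lists did so with medians of opposite sign in the replicates. Passing under every setting therefore does not show that the replicates agree. Leaving out each replicate in turn leaves 1 ratio and no test, hence no counts of genes. The surface mucous median then ran from -0.66 to -0.45, and of the lists that passed signs turned for the immune (-0.20 to 0.45), tuft (-0.65 to 0.11) and pancreatic lists (-2.28 to 0.27). Lists that did not pass also differed in sign between the replicates, among them the parietal (-0.45 and 0.19), fibroblast (0.21 and -0.66) and sex-linked lists (-1.17 and 0.22). Signs turned for Cpb1 (-4.66 to 0.89), Ctrc (-3.92 to 0.44), Pnlip (-3.95 to 0.50) and Try5 (-3.82 to 0.40).

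The count of 12 genes (5 higher, 7 lower) depended on the processing. It was 0 (0 higher, 0 lower) with median centring, with no filter (27366 genes), with the 4 arrays taken as independent, and with no replicate block (the RNAs unpaired). In these settings limma estimated the prior degrees of freedom at 2.62, 1.40, 2.40 and 2.76, against the infinite estimate of the main fit. The count was 7 (3 higher, 4 lower) with the stricter filter, 7 (2 higher) with an intensity trend, 8 (3 lower) with robust eBayes, 8 (3 lower) from the Cy5 arrays, 23 (11 higher, 12 lower) from the Cy3 arrays, 18 (9 higher) with every probe, 19 (10 higher) with probe means and 17 (15 higher, 2 lower) from Agilent's processed signals and from the deposited table, where 5 of the 12 genes were shared. At an adjusted p under 0.1 it was 18 (10 higher). Of the 12, 8 had the same sign on 4 arrays (3 lower). Without the GC trend it was 39 (21 higher, 18 lower), all 12 included, and with the replicate as a random block it was 1 (1 higher, 0 lower). With a dye term that fit was not run, since limma's estimate of its correlation then needs more than 4 arrays. Gast, Chia and Fcgbp each passed in 10 of 17 other settings, with means for Gast from -2.14 to -1.93. They did not pass from Agilent's processed signals or the deposited table, although their means there were about as large. Genes below background, such as Axin2 and Rspo3, have no usable ratio, and ratios of dim genes are drawn toward 0 by the offset. The calls of the stem marker, interferon, NF-kB, immune and red blood cell lists were lost in some settings (held in 16, 15, 15, 13 and 14 of 17), and the sex-linked list passed in 6. Over the 17 settings the other medians of lists that passed ran as follows: stem marker 0.09 to 0.37, chief -0.44 to -0.19, tuft -0.40 to -0.16, antimicrobial -0.51 to -0.07, intestinal -0.81 to -0.06, interferon -0.31 to -0.05, NF-kB -0.33 to -0.03, cholesterol -0.36 to -0.15, circadian -0.25 to -0.06, immune -0.01 to 0.24, red blood cell -1.17 to 0.01 and pancreatic -1.11 to -0.76. Where not named above, the cause was not tested. Median centring moved the median ratio of all genes to 0.13 (-0.18 in replicate 1 and 0.48 in replicate 2), and other changes under it are relative to that.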

Other observations

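Tests of exchanged labels, of an R-spondin effect on acinar genes and of a lower share of surface cells, and the reading of the GC test by replicate, were chosen after the result was seen, and so was the GC correction, with bounds written before it was run. Without the GC trend 39 genes passed limma's threshold, among them genes of division not named so far: Orc6 of the origin recognition complex (mean log2 ratio 1.35, adjusted p = 0.0386) and cyclin D2, Ccnd2 (1.31, adjusted p = 0.0454). Soat1, which esterifies cholesterol, stood at 1.35 (adjusted p = 0.0386). Chgb was lower at -1.32 and Hsph1 higher at 1.31. These genes were named after their values were seen.

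The Y-linked genes Ddx3y, Eif2s3y and Kdm5d had ratios of -1.17, -1.35 and -0.58 in replicate 1 and 0.06, 0.22 and 0.22 in replicate 2, and Xist was not well above background in any RNA.

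The ratios of the replicates did not correlate over all genes (r = -0.07). Exchanged labels in replicate 2 would turn its lists over. The S phase list had a median of at least 0.88 in each replicate and the endocrine list stayed below -0.69 in both. These lists were picked after the result, from a test on the mean of the replicates, which favours lists of the same sign in both. Of the lists that passed, the acinar (0.27 and -2.28), tuft (0.11 and -0.65) and immune (0.45 and -0.20) medians alone had opposite signs. With the sign of replicate 2 turned, 744 genes had an unadjusted limma p under 0.05, against 586 as labelled. Past the adjusted limma threshold were 0 genes, against 12 as labelled. Turning the sign also brings the opposite trends with probe GC content into the same direction, so these counts do not decide on an exchange. Since the lists were picked after the result, an exchange is not ruled out. Opposite trends with probe GC content go with part of the disagreement. Between 2 probes of the same gene (3339 genes) the ratio followed the GC difference with Spearman's rho of 0.12 (95% bootstrap interval 0.087 to 0.153) in replicate 1 and -0.16 (-0.196 to -0.132) in replicate 2. The distance of the probes to the 3' end was not worked out, so GC content and probe position cannot be told apart. Removing the trend moved the correlation of the replicates from -0.07 to 0.047, so most of the disagreement stays open, and RNA quality may be part of it.

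Pancreatic acinar genes were low as a list in replicate 2, and 4 of the 12 were lower in both replicates. The median of 0.27 in replicate 1 shows no fall of these genes as a list there. It rests on 1 RNA pair in which they were dim, with median log2 levels of 7.67 with R-spondin and 7.33 with PBS. Because the test was also chosen after the result, it does not decide on an effect of R-spondin. The median level also differed between the 2 PBS RNAs, 11.6 in replicate 2 against 7.33 in replicate 1. R-spondin cannot have made that difference. Pancreatic tissue in the PBS RNA of replicate 2 is a candidate explanation: the acinar median there was 2.84 (log2) above the next highest RNA, with Cpb1 at 11.96 against 7.31 in the R-spondin RNA of that replicate. It stays open because the other 3 RNAs, predicted to lie within 1 of each other, ranged from 7.33 to 8.73. Of the 12 acinar genes measured 8 were above background in both RNAs of replicate 1, and 0 belong to another list.

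S phase genes were high and endocrine genes low in both replicates. Without the GC trend the S phase list kept 90.4% of its mean median and the endocrine list 98.4% (83.9% and 78.7% less 1 SE, above the bound written before), which argues against that trend as the whole cause. Opposite trends cancel in part in the mean, and by replicate the smallest share was 76.8%, for S phase in replicate 2 (1.00 to 0.77); this is over 50% less 1 SE, but had the written bound been asked of each replicate less 1 SE, the test would have left the trend open, with 66.4% there and 72.5% for the endocrine list. A lower share of surface mucous cells would by itself raise markers of every other type and so leaves the endocrine fall unexplained. The endocrine median, -0.695 or lower in either replicate, is part of the pattern, so this test could not have come out otherwise. It does not tell whether a lower share adds to the S phase rise. A response of the antral glands to R-spondin, the difference that the design names, may account for the S phase rise and the endocrine fall. It stays a hypothesis, since other differences between the RNAs of a pair are untested.

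Because Mcpt1, Cma1, Mcpt2 and Mcpt4 were high, more mast cell RNA in the R-spondin RNAs was tested on 15 other mast cell genes written down first, none of them in another list. Of these 8 were measured, with medians of 0.48 in replicate 1 and 0.23 in replicate 2 (SE over genes 0.12). The lower median misses the 0.5 that more mast cell RNA was said to need, and by the bound of 0.25 as written it would count against the hypothesis. The allowance of 1 SE around each list's bound was added after this value was seen, and with it the hypothesis stays open. The abundant mast cell gene Cpa3 had ratios of 1.51 and 0.81 and Kit of -0.10 and 0.03. Apart from Cpa3 (mean log2 intensity 7.64) and Rab27b (10.4, ratios of -1.48 and 0.41), the measured genes were dim, at 6.46 to 7.05. The offset draws ratios of dim genes toward 0, so the medians may understate a rise.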
